A study of Mus musculus with 20 samples.

How the data were processed

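The study measured total RNA from aortic endothelium of female Apoe-/- mice with 5/6 nephrectomy, in 20 libraries from 5 treatment groups of 4. Per the labels' protocols, RNA was collected by shearing the endothelium off the aorta with qiazol and libraries were made with a Nugen Ovation kit. Each library carries its own animal number in the labels, so the replicates of a group are separate mice, and no number occurs in 2 groups. The labels give no batch, date or litter.

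The authors deposited a table of variance-stabilized read counts on a log2 scale for 20442 genes. Per the submitters' processing notes, the tools were cutadapt 1.16, STAR 2.5.3a, FastQC, featureCounts 1.15.29 and DESeq2 1.18.1 with build GRCm38.p5, listed without roles. The authors also deposited FPKM (fragments per kilobase of gene and M reads) for 32081 genes with their symbols and lengths. The strand of counting, the annotation release and the treatment of reads with several matches were not given in the sources used here. Antisense genes, pseudogenes and genes overlapped by another gene, among those named by their p or always named, are therefore reported as uncertain. Members of gene lists were not checked for overlap.

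Whole reads were recovered from FPKM, gene length and 1 step per library. In genes of up to 3000 bases with up to 1000 reads, 100% of the values checked lay within 0.1 of a whole number in every library. These reads gave the depth, 11.6 to 21.4 M (mega) assigned reads per library. Size factors, started from median ratios, and the constants of a variance-stabilizing formula were fitted to the deposited log2 values. With them the reads gave 99.993% of the deposited values to within 1e-06, with a largest difference of 0.011. This is the closeness of a fit to those same values. On that scale a step from 10 to 20 normalized reads moves the value by 0.4 and a step from 100 to 200 by 0.81, so differences of weakly expressed genes are compressed. FPKM is divided by all assigned reads, ribosomal ones included, so libraries rich in ribosomal reads have lower FPKM in all other genes.

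Differences were fitted with limma 3.58.1 in R 4.3.3 on the deposited variance-stabilized values. The model held 5 group means over all 20 libraries, with 15 residual degrees of freedom, and moderated variances with a mean trend. A gene was tested if its mean FPKM was at least 0.5, which left 16848 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Each HDL-based group was compared with HDL, HDL with saline, and the dual group with each single inhibitor and with saline. Further tests were LNA489 against LNA92a, a non-additive contrast (dual minus both single groups plus HDL) and an F-test over the 5 groups. All tests were 2-sided. No paired test was used because the animal numbers differ between groups. The table design anticipated a count test only for a table of raw counts, which the deposited files are not, so none was run. Limma's voom on the recovered reads was added instead.

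The text names genes by a fixed rule. In each of the 4 main comparisons these were to be the 10 genes with the largest difference in each direction among called genes with a symbol and a mean FPKM of at least 1. Where fewer than 5 passed, the direction was filled to 5 with the smallest p, as values only. Secondary comparisons and the non-additive contrast used 5 and 3 in place of 10 and 5. Up to 4 members with the smallest p were taken from each described list, and Apoe, Mir17hg, Calcr, Mir92-1, Mir489, Tgfb2, Klf2, Klf4 and Itga5 were always named. Coordinates are 1-based positions from GENCODE M21 on GRCm38. Of the gene identifiers, 31903 matched that release without their version, 27384 with the same version, and 30601 had the same symbol.

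Fixed gene lists, 29 in all with 584 genes of which 554 were tested, were compared with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The 11 cell type lists were endothelial, vascular smooth muscle, fibroblast and adventitia, macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil, erythroid and platelet, adipocyte, striated and cardiac muscle, and neuron and Schwann cell. The 16 pathway lists were endothelial adhesion and chemokine, interferon response, antigen presentation, flow-responsive endothelial quiescence, TGF-beta signalling and endothelial-to-mesenchymal transition, extracellular matrix, cholesterol biosynthesis and uptake, cholesterol efflux and LXR, fatty acid oxidation and PPAR, oxidative phosphorylation, cell cycle, immediate early and dissociation stress, unfolded protein response, circadian clock, angiogenesis and Notch, and oxidative stress and hypoxia. The 2 target lists held reported targets of miR-92a-3p and of miR-489-3p. The lists, the tests, the threshold and the gene rule were set before the data were examined.

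Cell type list means per library were compared between groups with an exact permutation test, 4 libraries against 4, whose smallest possible p is 0.0286. The 6 relations between list means across the 20 libraries were tested with 100000 permutations. Genes with a microRNA site were found by searching the annotated 3' UTRs for the 7-base match to each seed, GTGCAAT for miR-92a-3p and GTGTCAT for miR-489-3p, beside 100 control 7-mers with the same bases. Both seeds were taken from memory, and for miR-489-3p a start moved by 1 base was tried too. Comparisons that share the HDL libraries were set beside 100 simulations of unchanged groups and 6 splits of the HDL libraries. Other splits of the same libraries were refitted, 35 per pair of groups and 100 for wider contrasts.

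The fit was tested on simulated reads and on the real libraries with thinned reads, each with 200 genes changed by 2, 4 or 8-fold. The changed genes were drawn from those with a mean of at least 20 normalized reads, so the shares do not cover weaker genes. In simulated reads with the spread of the real libraries and 16848 genes, it recovered 16.4%, 47.8% and 75.8% of the genes changed by those folds in HDL against saline. The shares were 25.4%, 41.8% and 66.7% in LNA92a against HDL, 19.4%, 68.7% and 77.3% in LNA489 against HDL, and 16.4%, 55.2% and 78.8% in the dual group against HDL. With thinned real reads the shares were 11.9%, 50.7% and 66.7% in HDL against saline. They were 13.4%, 35.8% and 63.6% for LNA92a, 19.4%, 55.2% and 74.2% for LNA489, and 20.9%, 50.7% and 72.7% for the dual group, each against HDL.

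Alternatives chosen beforehand changed the low-expression filter, the values (log2(FPKM + 0.1) and log2(FPKM + 1)), the groups in the fit, the variance moderation, library weights (arrayWeights), the centring, the threshold and the smooth muscle list mean as a covariate. Each library was also left out in turn. Added after seeing the data were voom, the endothelial, adipocyte, macrophage and B cell list means as 4 covariates, leaving aside 3 libraries (HDL 11, Saline 2 and dual 10), and a fit on libraries whose endothelial mean exceeded their adipocyte mean. The mature microRNAs and the genes Mir92-1 and Mir489 were not analysed here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.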

Results

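RNA of the aortic endothelium was sequenced in 20 female Apoe-/- mice with 5/6 nephrectomy, a surgery that leaves the animal with chronic kidney disease. Per the labels, surgery was at 9 weeks of age and 1 retro-orbital treatment followed 7 weeks later, with collection 1 week after that. The 5 groups of 4 mice received saline, HDL (4 mg), HDL + LNA92a, HDL + LNA489, or HDL with both inhibitors, called the dual group here. LNA92a and LNA489 are locked nucleic acid inhibitors of miR-92a-3p and miR-489-3p, given at 20 mg/kg each, so the dual group received 40 mg/kg of LNA in total. Libraries are named by group and animal number (HDL 11), and "LNA92a" and "LNA489" stand for the groups that also received HDL.

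Assigned reads numbered 12.6 to 17.4 M per saline library, 12.4 to 15.9 M for HDL, 11.6 to 17.8 M for LNA92a, 12.9 to 19.9 M for LNA489 and 13.3 to 21.4 M for the dual group (M, mega). Between 17378 and 23365 genes had a read. The 18S ribosomal RNA gene Rn18s-rs5 took 16.5% ± 7.16 (SD, n = 4) of the reads in LNA92a and 7.07% ± 2.71 in HDL. FPKM, which divides by all assigned reads, was lower across genes in LNA92a. On log2(FPKM + 0.1), the median of all genes was -0.471 in LNA92a against HDL, and it was -0.056 on the variance-stabilized scale. The same shift was 0.345 for LNA489 against LNA92a, 0.448 and 0.109 for the dual group against LNA92a and LNA489, and 0.593 for the non-additive contrast. Median-centring moved LNA489 against HDL to -0.113. Log2 differences are differences of mean variance-stabilized values with their SE from limma, and FPKM values are means ± SD of 4 mice.

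Endothelial genes made up very different parts of the libraries. Pecam1, the endothelial adhesion molecule, ranged from 10.8 FPKM in HDL 4 to 1010 FPKM in HDL 23, and Vwf, the clotting factor stored in endothelial cells, from 3.02 in HDL 4 to 316 in Saline 24. The fat hormone gene Adipoq ran from 3.33 FPKM in Saline 9 to 373 in LNA92a 12, and Ucp1, the uncoupling protein of brown fat, from 11.1 to 1230 in those same libraries. The macrophage genes Lyz2 (418 to 8450 FPKM, highest in LNA489 13) and Gpnmb (7.94 in LNA92a 5 to 1580 in Saline 9) also varied. These marker genes were chosen after their values were seen. The B cell gene Ms4a1 reached 61.1 FPKM in HDL 11 against a median of 2.33, and that library had the highest B and plasma cell list mean (11.94) and the lowest macrophage list mean (9.23). The endothelial list mean exceeded the adipocyte list mean in 9 of the 20 libraries (2 saline, 3 HDL, 2 LNA92a, 1 LNA489 and 1 dual).

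**Figure D1:**
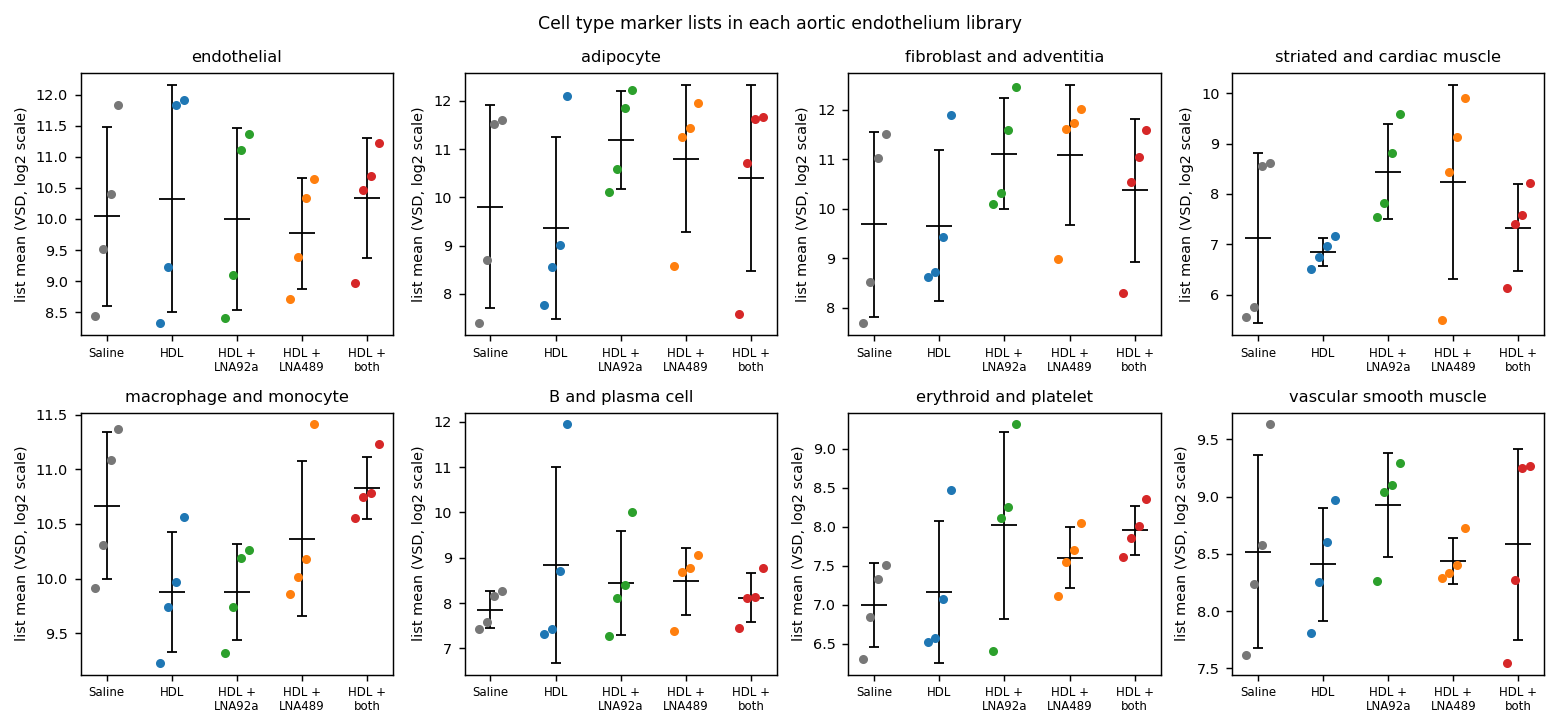
Mean variance-stabilized value (log2 scale) of 8 cell type marker lists in each library, by treatment group, where points are libraries and bars are the mean and SD of 4 mice. Libraries of 1 group differ by several log2 units, as in HDL, where the adipocyte mean ran from 7.78 to 12.09.

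Marker lists moved together across the libraries. Among the 6 relations tested, the adipocyte and fibroblast list means had Pearson's r = 0.97 and Spearman's rho = 0.91, and the adipocyte and oxidative phosphorylation means had r = 0.97 and rho = 0.96. The macrophage and cholesterol efflux means had r = 0.92 and rho = 0.83. For these 3 relations each permutation p was 1e-05, the smallest that 100000 permutations can give, with adjusted p = 2e-05. Without the 2 farthest libraries r was 0.96, 0.97 and 0.89, and with group means removed it was 0.98, 0.97 and 0.88. Adipocyte and endothelial means were inversely related (r = -0.67, permutation p = 0.00145, adjusted p = 0.00217; rho = -0.68, permutation p = 0.0012, adjusted p = 0.0018). That r was -0.70 without the 2 farthest libraries and with group means removed. Striated muscle and oxidative phosphorylation means had r = 0.66 (permutation p = 0.00186, adjusted 0.00223) and rho = 0.58 (permutation p = 0.00852, adjusted 0.0102), with r = 0.70 without 2 libraries and 0.61 within groups. Endothelial and B cell means showed no relation (r = -0.10, permutation p = 0.707; rho = -0.04, permutation p = 0.866; the adjusted values were the same, and r was -0.20 and -0.11 on those checks).

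Treatment group explained little of the differences among libraries. The first principal component held 45.3% of the variance and set Pck1 and Cidea, genes of fat, and the resident macrophage gene Cd163 against the endothelial genes Gja5, Sox17, Vwf and Nos3 and the myeloid genes Mmp12 and Itgax. Group membership accounted for 14.8% of it (permutation p = 0.62). The second component held 11.5% of the variance, with Ighg2c and Ms4a1 at 1 end and HDL 11 farthest out, and groups accounted for 4.1% (permutation p = 0.971). The third held 7.7%, with the adrenal steroid genes Hsd3b1 and Cyp21a1 at 1 end, and groups accounted for 30.4% (permutation p = 0.219). Across genes, the median share of variance between groups was 16%. With no effect at all the mean share is 21.1%, a mean set beside a median, so the gap between them is not a measure of its own. Correlations between libraries had a median of 0.92 within a group and 0.925 between groups.

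**Figure D2:**
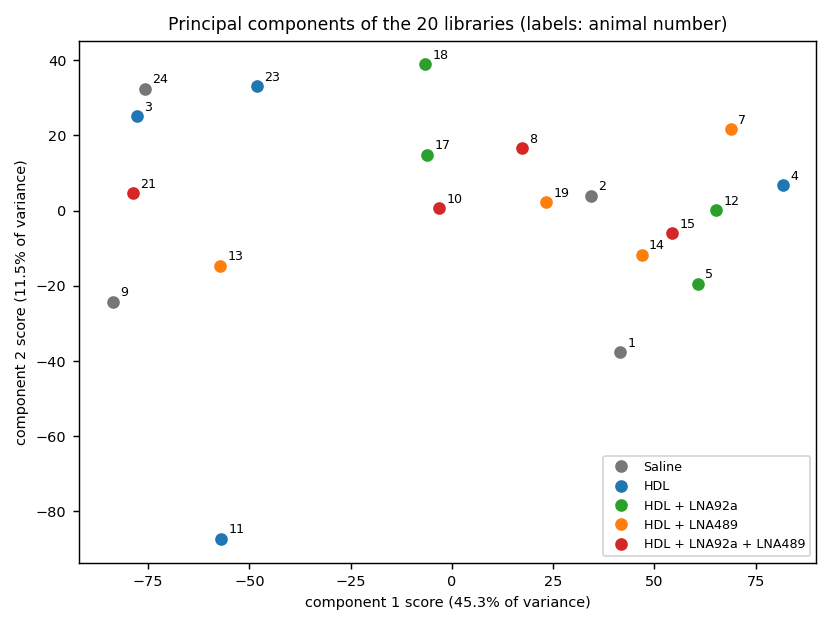
Scores of the 20 libraries on principal components 1 (45.3% of the variance) and 2 (11.5%), coloured by group and labelled by animal number. The 5 groups overlap on component 1, and HDL 11 lies apart on component 2.

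In exact permutation tests of the 11 cell type list means over 5 pairs of groups, 0 of 55 passed an adjusted p of 0.05 (smallest adjusted p 0.786). A list could pass only if many tests reached the smallest possible exact p together, so this outcome was nearly fixed by the design. The smallest exact p possible with 4 against 4 mice, 0.0286, was reached by erythroid and platelet genes in the dual group against saline (a difference of 0.96) and by striated and cardiac muscle genes in LNA92a against HDL (1.59). Macrophage genes were 0.95 higher in the dual group (10.83 ± 0.29) than in HDL (9.88 ± 0.55), with an exact p of 0.0571. On log2(FPKM + 0.1) the exact p was 0.0286 for these macrophage genes and 0.0571 for the erythroid and for the muscle difference, so the scale decided which list reached the smallest p.

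The inactivated gene Apoe, which encodes apolipoprotein E, was still read as transcript in every library. Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188) measured 13.7 ± 10.1 FPKM in saline, 11.5 ± 8.01 in HDL, 5.27 ± 4.14 in LNA92a, 7.05 ± 3.38 in LNA489 and 15.4 ± 6.48 in the dual group. The gene-level values do not separate the disrupted allele from an intact one, so they do not check the genotype. Mir17hg (chromosome 14, 115042879 to 115046727), the host transcript of the miR-17-92 cluster that holds Mir92-1, measured 1.90 ± 1.02, 2.72 ± 1.97, 1.00 ± 0.513, 1.5 ± 0.761 and 1.84 ± 1.24 FPKM in the same order. Calcr (chromosome 6, 3685680 to 3764714), the calcitonin receptor gene that hosts Mir489, had 0 to 5 reads per library and was not tested. The microRNA genes Mir92-1 and Mir489 were not analysed here.

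Klf2 and Klf4 encode transcription factors that laminar flow raises in endothelium, and Klf2 (chromosome 8, 72319033 to 72321656) was lowest in saline. It measured 42.5 ± 25.0 FPKM in saline, 92.2 ± 38.9 in HDL, 62.4 ± 41.3 in LNA92a, 57.4 ± 29.5 in LNA489 and 87.9 ± 61.8 in the dual group. Klf4 (chromosome 4, 55527143 to 55532466) measured 25.2 ± 10.9, 36.1 ± 21.6, 37.2 ± 18.3, 32.0 ± 15.1 and 42.8 ± 27.2 FPKM. The fibronectin receptor subunit Itga5 (chromosome 15, 103344286 to 103366763) measured 40.8 ± 36.6, 49.1 ± 47.8, 20.6 ± 16.5, 24.4 ± 19.1 and 36.4 ± 24.7 FPKM. Tgfb2 (chromosome 1, 186622792 to 186705989), a growth factor and listed miR-489-3p target, measured 1.42 ± 0.508, 1.66 ± 0.624, 2.21 ± 0.727, 4.15 ± 3.51 and 2.65 ± 0.952 FPKM, with 9.39 in LNA489 14. None of these genes passed the threshold in any comparison, and Itga5, Tgfb2 and Mir17hg are uncertain because other genes overlap them.

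**Figure D3:**
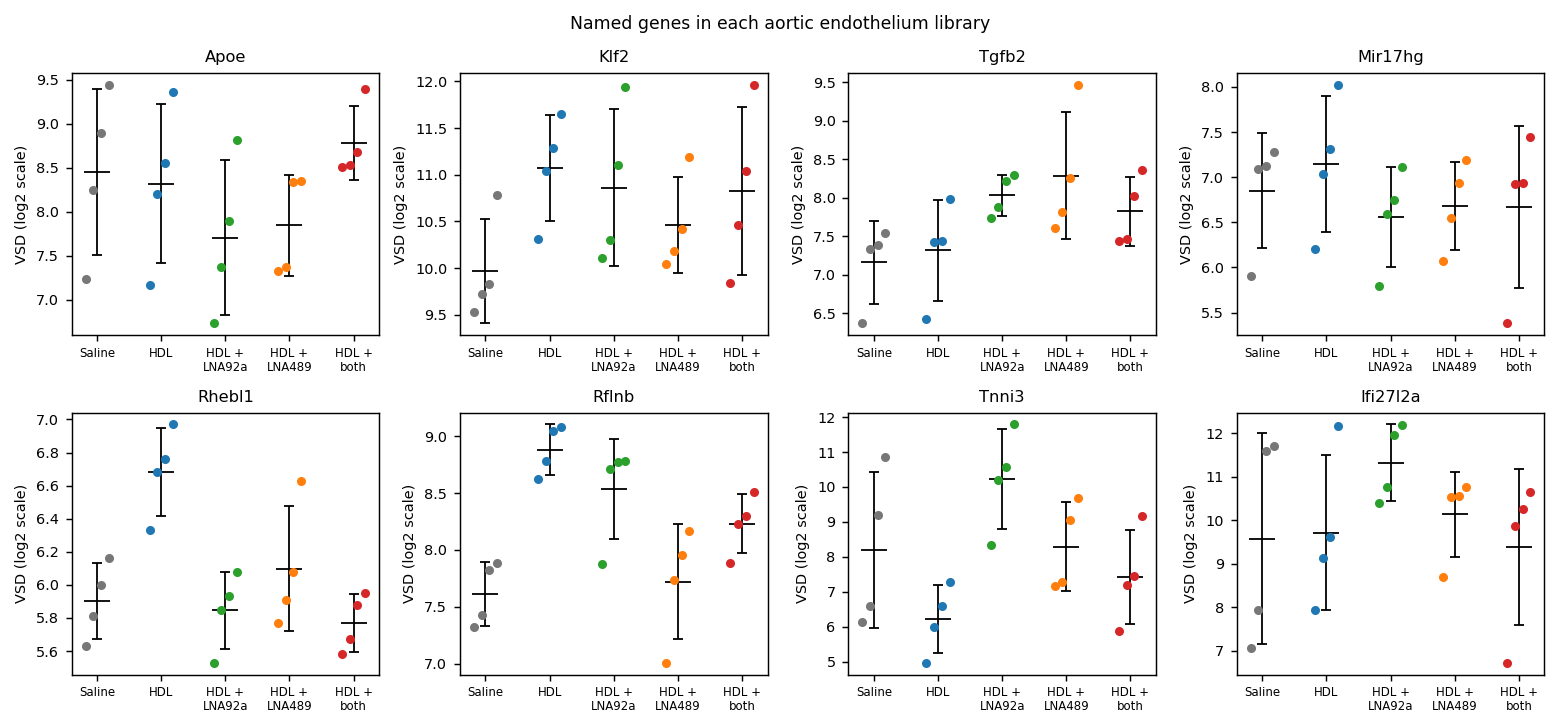
Variance-stabilized value (log2 scale) of 8 named genes in each library by treatment group, with points for libraries and bars for the mean and SD of 4 mice. The 4 HDL libraries lie above the saline libraries for Rflnb, and HDL 4 and HDL 3 are far apart for Ifi27l2a (592 and 34.3 FPKM).

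HDL against saline asks what the lipoprotein alone does to the endothelium of these mice. Rflnb, which encodes a filamin-binding regulator of actin, was 9.45 ± 2.66 FPKM in HDL and 3.42 ± 0.931 in saline (ENSMUSG00000020846.6, chromosome 11, 76019194 to 76027782), a log2 difference of 1.27 ± 0.26. Spns2, the sphingosine 1-phosphate exporter of endothelial cells, was 7.87 ± 0.789 and 3.73 ± 1.02 FPKM (0.99 ± 0.29). Klf2 was higher in HDL by 1.11 ± 0.46, with 4 of 4 HDL mice above the saline mean on that scale and 3 of 4 in FPKM, where HDL 4 had 39.6. On the other side, Dhrs3, a retinaldehyde reductase, was 16.5 ± 6.4 FPKM in HDL and 40.7 ± 23.8 in saline (-1.19 ± 0.35), and the macrophage receptor gene Adgre1 was 8.94 ± 2.41 and 21.6 ± 8.66 (-1.15 ± 0.42).

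No single gene was called: limma gave 0 of 16848 genes at adjusted p under 0.05. At unadjusted p under 0.05 there were 281 (159 higher, 122 lower), where chance gives 842 on average. Voom called 0 (308 unadjusted) and arrayWeights 0 (899 unadjusted), and the smallest adjusted p in limma was 1. The 281 became 556 without Saline 24, 443 without HDL 3, 656 without HDL 4 and 451 without HDL 11. In 164 genes (0.97%) the 4 HDL mice did not overlap the 4 saline mice, and chance gives 2.86%. The other genes with the smallest p, given as values only, were Snord104 (a small nucleolar RNA, 1.05 ± 0.29), Rhebl1 (a GTPase of the mTOR pathway, 0.78 ± 0.23) and the zinc finger gene Zfp507 (0.69 ± 0.21) on the higher side. The lower ones were the kinase A subunit Prkar1b (-0.93 ± 0.30), the matrix gene Mamdc2 (-1.82 ± 0.61), the kinase gene Cdk20 (-1.21 ± 0.42) and the cell cycle inhibitor Cdkn1c (-1.87 ± 0.66; 12.5 ± 5.49 against 72.1 ± 77.2 FPKM). Another annotated gene overlaps Spns2, Rhebl1, Zfp507, Prkar1b, Mamdc2, Cdk20 and Cdkn1c, so their reads are uncertain. Klf4 (0.37 ± 0.54), Tgfb2 (0.16 ± 0.40), Mir17hg (0.30 ± 0.46), Apoe (-0.13 ± 0.51) and Itga5 (-0.17 ± 0.93) differed by less than 2 times their SE. At the median SE of 0.36, a gene needed a difference of 0.75 to reach an unadjusted p of 0.05.

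Macrophage genes were lower and B cell genes higher in HDL than in saline as groups with the preset correlation, and neither call held with an estimated one. In exact permutation tests of the list means, the macrophage difference was -0.79 (exact p = 0.171) and the B cell difference 0.99 (exact p = 0.514). All 35 splits of these libraries called 4 or more lists with the preset correlation. The macrophage and monocyte list had a median of -0.97 with 17 of 18 genes lower (camera adjusted p = 2.50e-08; adjusted p = 0.499 with an estimated correlation), led by Adgre1, C1qb (-1.10 ± 0.58), C1qc (-0.95 ± 0.53) and C1qa (-0.72 ± 0.40), the last 3 coding for complement C1q. The B and plasma cell list had a median of 1.10 with 13 of 14 genes higher (adjusted p = 5.17e-05; 0.844 with an estimated correlation), among them the joining chain Jchain (1.77 ± 0.82), the immunoglobulin light chain Igkc (1.48 ± 0.96) and Cd79b (1.39 ± 0.75). Cholesterol efflux genes, with the lipid transfer protein Pltp (-1.09 ± 0.48; 62.1 ± 35.7 against 136 ± 94.1 FPKM), the HDL receptor Scarb1 (-1.13 ± 0.63) and the ester hydrolase Nceh1 (-1.01 ± 0.62), had a median of -0.22 with 12 of 15 lower (adjusted p = 0.0163; 0.759 with an estimated correlation). Cell cycle genes such as Birc5 (-0.93 ± 0.61) and Top2a (-0.83 ± 0.86) had a median of -0.18 with 24 of 30 lower (adjusted p = 0.0318; 0.844 with an estimated correlation). None of the members passed the threshold, over all genes or adjusted over the list alone, and fry called 0 lists.

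The B cell difference came from HDL 11: without it the B cell median was 0.02, cholesterol efflux -0.10 and cell cycle -0.68, and the first 2 calls ended. The B cell median was 1.67 without HDL 3. The macrophage call held on leaving out any of the 8 libraries, with medians of -1.26 to -0.65. The cell cycle call ended without Saline 1 (-0.22), Saline 9 (0.02), HDL 3 (-0.16), HDL 4 (0.16) or HDL 23 (-0.14), and the median was -0.46 without Saline 2. Cholesterol efflux lost its call without Saline 2 (-0.20), which held 2160 FPKM of 7 adrenal cortex genes where the other saline libraries held 2.75 to 8.61, or without Saline 9 (-0.24), and was -0.42 without Saline 1, -0.35 without Saline 24, -0.39 without HDL 4 and -0.47 without HDL 23. In place of 4 called lists there were 7 without Saline 2, 11 without Saline 9, 13 without Saline 24, 14 without HDL 4 and 10 without HDL 11.

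Lists that were not called had medians of 0.26 for endothelial genes (adjusted p = 0.32), 0.21 for interferon response (0.0779), 0.26 for flow-responsive quiescence (0.404), 0.21 for adhesion and chemokine genes (0.226), 0.21 for TGF-beta signalling (0.153) and -0.15 for cholesterol biosynthesis (0.0626). T and NK cell, adipocyte, fatty acid oxidation, oxidative phosphorylation and erythroid genes, with medians of -0.56, -0.46, -0.28, -0.25 and 0.27, were not called either. The reported miR-489-3p targets had a median of 0.23 (0.077), neutrophil genes 0.06 (0.671), neuron and Schwann cell genes 0.00 (0.742) and immediate early genes 0.12 (0.404). Sign differed between the median, the mean and the test for fibroblast (0.03, -0.02, down), circadian clock (0.22, 0.02, down), angiogenesis and Notch (0.06, -0.02, down) and miR-92a-3p targets (0.01, -0.01, down). The heme enzyme Hmox1 was 26.4 ± 11.1 FPKM in HDL and 79.8 ± 53.1 in saline (-1.37 ± 0.61), and the NF-kappaB inhibitor Nfkbia was higher by 0.78 ± 0.32.

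LNA92a against HDL asks what the miR-92a-3p inhibitor adds to HDL, without a control LNA. Among genes with the smallest p, none of them past the threshold, the cardiac troponin Tnni3 (ENSMUSG00000035458.15, chromosome 7, 4518305 to 4524229) was 44.3 ± 38.8 FPKM in LNA92a and 2.12 ± 1.91 in HDL, a log2 difference of 4.01 ± 0.98. Hrc, a calcium-binding protein of the sarcoplasmic reticulum (chromosome 7, 45335290 to 45338974), was 3.33 ± 1.79 and 0.274 ± 0.491 FPKM (2.66 ± 0.64). Pcp4l1, a calmodulin-binding protein relative (chromosome 1, 171173262 to 171196268), was 6.46 ± 4.69 and 1.13 ± 0.145 (1.84 ± 0.43). The saline libraries, which received no inhibitor, had 1.56 to 57 FPKM of Tnni3, 0.112 to 4.09 of Hrc and 1.27 to 8.29 of Pcp4l1, each highest in Saline 2. Over all libraries Tnni3 ran from 0.152 in HDL 4 to 98.7 in LNA92a 18. The source of these transcripts was not tested. The histone demethylase gene Kdm4b was 5.05 ± 0.521 and 10.6 ± 2.62 FPKM (-0.57 ± 0.17).

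Limma called 0 genes in this comparison, with 595 at unadjusted p under 0.05 (251 higher, 344 lower) and a smallest adjusted p of 0.867. Voom called 0 (488 unadjusted) and arrayWeights 0 (3208 unadjusted). The 595 became 2860 without HDL 4, 325 without HDL 11 and 389 without LNA92a 5, and 2201 on log2(FPKM + 0.1). In 374 genes (2.22%) the 2 groups did not overlap, where chance gives 2.86%. Other genes with small p were Pln, the cardiac calcium pump regulator (2.68 ± 0.66), the cardiac stress gene Ankrd1 (3.62 ± 0.90) and Rhebl1 (-0.84 ± 0.23; 0.784 ± 0.276 against 2.63 ± 0.385 FPKM). The antisense genes Gm17151 (-1.16 ± 0.28) and Gm20692 (-1.04 ± 0.29) and the unclassified Gm43815 (-1.06 ± 0.29) lie over coding genes and are uncertain, as are Tnni3, Pln and Rhebl1, which other genes overlap. Tgfb2 (0.71 ± 0.40), Klf4 (0.55 ± 0.54), Klf2 (-0.21 ± 0.46), Itga5 (-0.33 ± 0.93), Mir17hg (-0.58 ± 0.46) and Apoe (-0.62 ± 0.51) were not called. Itga5 is a reported miR-92a-3p target.

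Mitochondrial, fat, fibroblast and muscle genes were higher in LNA92a than in HDL as groups with the preset correlation, and none of these calls held with an estimated one. Oxidative phosphorylation genes had a median of 1.3 with 26 of 26 higher (camera adjusted p = 5.76e-12; 0.802 with an estimated correlation), led by the cytochrome oxidase subunits Cox7b (1.83 ± 0.89), Cox4i1 (1.43 ± 0.73) and Cox5a (1.37 ± 0.67; 28.1 ± 13.4 against 16.7 ± 17.1 FPKM). Mitochondrially encoded genes took 16.6% ± 5.53 of reads in LNA92a (10.55 to 23.96%) and 8.66% ± 8.82 in HDL, where HDL 4 had 21.76% and the others 3.23 to 5.95%. Adipocyte genes had a median of 1.99 with 16 of 16 higher (adjusted p = 1.52e-07; 0.802 with an estimated correlation), with the brown fat genes Dio2 (2.00 ± 1.01) and Cox8b (2.44 ± 1.26) and the fatty acid carrier Fabp4 (2.03 ± 1.11). Fibroblast genes, including Fbln1 (2.21 ± 1.16), Dpt (2.33 ± 1.36) and decorin, Dcn (1.72 ± 1.02), had a median of 1.59 with 16 of 16 higher (adjusted p = 3.44e-06; 0.802 with an estimated correlation). Striated and cardiac muscle genes had a median of 1.23 with 10 of 14 higher (adjusted p = 4.48e-06; 0.802 with an estimated correlation). They held the cardiac myosin Myh6 (4.78 ± 1.23), the troponin Tnnt2 (4.24 ± 1.14) and the myosin-binding protein Mybpc3 (2.27 ± 0.67), and 5 members passed the threshold adjusted over the list alone, against 0 over all genes.

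Smaller shifts were called in 6 further lists. Fatty acid oxidation genes such as Fabp3 (1.90 ± 1.09) and the fatty acid receptor Cd36 (1.05 ± 0.61) had a median of 1.13 (adjusted p = 0.000494; 0.802 with an estimated correlation). Erythroid and platelet genes, with the chemokine Pf4 (1.57 ± 0.74) and the globin Hba-a1 (1.68 ± 0.95), had a median of 0.88 (adjusted p = 0.000425; 0.802 with an estimated correlation). Extracellular matrix genes such as Col12a1 (1.5 ± 0.85) and Loxl1 (1.60 ± 0.91) had a median of 0.47 (adjusted p = 0.00903; 0.802 with an estimated correlation), and vascular smooth muscle genes such as Itga8 (0.93 ± 0.53) and Des (1.91 ± 1.12) a median of 0.46 (adjusted p = 0.00944; 0.802 with an estimated correlation). Antigen presentation genes, with Tap2 (-0.42 ± 0.26) and H2-K1 (-0.36 ± 0.29), had a median of -0.31 with 16 of 16 lower (adjusted p = 0.0218; 0.802 with an estimated correlation). T and NK cell genes, with the receptor Ncr1 (-0.47 ± 0.39), had a median of -0.50 with 17 of 17 lower (adjusted p = 0.0463; 0.899 with an estimated correlation). With an estimated correlation 0 of the 10 lists stayed past the threshold, and fry called 0.

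Single libraries decided the weaker of these calls. Without HDL 11 the medians were 0.04 for T and NK cell, 0.07 for antigen presentation, 0.07 for smooth muscle and -0.05 for matrix genes, and those calls ended, while erythroid genes had 0.46 and fatty acid oxidation 0.72. Without HDL 4 the erythroid call ended (0.48) and medians were 1.97 for oxidative phosphorylation, 2.46 for fibroblast, 1.89 for fatty acid oxidation, -0.57 for antigen presentation and -1.24 for T and NK cell genes. Leaving out LNA92a 12 ended the calls of matrix (0.05), smooth muscle (0.28) and T and NK cell genes (-0.22), with fibroblast genes at 1.04. Without LNA92a 18 the calls of erythroid (0.16), antigen presentation (-0.25) and T and NK cell genes (-0.44) ended. The T and NK cell call also ended without HDL 3 (-0.38), HDL 23 (-0.46) or LNA92a 17 (-0.42), with -0.85 without LNA92a 5, and the smooth muscle median was 0.45 (call ended) without LNA92a 17 and 0.73 without HDL 3.

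The reported miR-92a-3p targets had a median of -0.23 (adjusted p = 0.248; adjusted p = 0.802 with an estimated correlation), where an inhibitor would raise targets. Map2k4, a stress kinase, was -0.45 ± 0.17 (5.72 ± 1.61 against 10.6 ± 1.94 FPKM), the lipid phosphatases Mtmr4 -0.45 ± 0.24 and Plpp3 0.76 ± 0.44, and the death gene Bcl2l11 -0.47 ± 0.36. Endothelial genes had a median of -0.32 (adjusted p = 0.474), B and plasma cell genes -0.42 and adhesion and chemokine genes -0.37 (0.229). Sign differed between the median, the mean and the test for macrophage (-0.06, 0.00, up), flow-responsive quiescence (-0.04, -0.03, up), angiogenesis (-0.09, -0.09, up) and immediate early genes (0.00, -0.01, down).

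LNA489 against HDL asks what the miR-489-3p inhibitor adds to HDL, again without a control LNA. Rflnb was 3.75 ± 1.51 FPKM in LNA489 and 9.45 ± 2.66 in HDL, a log2 difference of -1.16 ± 0.26, so that LNA489 lay near saline. The listed miR-489-3p target Tgfb2 was higher by 0.97 ± 0.40, with 9.39 FPKM in LNA489 14 and 2.17 to 2.81 in the others. Megf9, a transmembrane protein with EGF-like repeats, was 8.51 ± 3.13 and 3.37 ± 1.94 FPKM (1.36 ± 0.40), and Cep290, a protein of the cilium base, 2.90 ± 0.55 and 1.56 ± 0.164 (0.81 ± 0.24). The chromatin gene Zmym3 was 2.23 ± 0.645 and 4.24 ± 1.10 FPKM (-0.80 ± 0.20).

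Limma called 0 genes here too, with 638 at unadjusted p under 0.05 (223 higher, 415 lower) and a smallest adjusted p of 0.92. Voom called 0 (676 unadjusted) and arrayWeights 0 (3169 unadjusted), and 260 genes (1.54%) did not overlap against 2.86% by chance. The 638 became 2297 without HDL 4, 1317 without LNA489 13 and 366 without LNA489 7. Other genes with small p were Hrc (2.15 ± 0.64), the zinc finger gene Zfp770 (0.74 ± 0.22), Prkar1b (0.99 ± 0.30) and E4f1, a ubiquitin ligase and transcription factor (-0.88 ± 0.23). The pseudogene Akirin1-ps (-1.21 ± 0.25) and the antisense gene Gm44623 (-1.11 ± 0.27) are uncertain, and other genes overlap Cep290, Prkar1b and Tgfb2. Klf4 (-0.08 ± 0.54), Klf2 (-0.61 ± 0.46), Itga5 (-0.29 ± 0.93), Mir17hg (-0.46 ± 0.46) and Apoe (-0.48 ± 0.51) were within 2 SE of 0.

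Fibroblast, fat and muscle genes were higher in LNA489 than in HDL as well with the preset correlation, and none of these calls held with an estimated one. Fibroblast genes had a median of 1.55 with 16 of 16 higher (camera adjusted p = 3.34e-06; 0.68 with an estimated correlation), among them Fbln1 (2.22 ± 1.16), the collagen Col1a1 (1.54 ± 0.92) and Tcf21 (1.10 ± 0.60). Adipocyte genes had 1.47 with 16 of 16 higher (adjusted p = 8.14e-06; 0.68 with an estimated correlation), including the lipase Lpl (1.47 ± 0.67; 172 ± 64.9 against 91.9 ± 100 FPKM) and Dio2 (2.11 ± 1.01). Striated and cardiac muscle genes had 1.48 with 14 of 14 higher (adjusted p = 8.14e-06; 0.68 with an estimated correlation), with Tnni3 (2.08 ± 0.98), Myh6 (2.45 ± 1.23) and the creatine kinase Ckm (1.72 ± 1.01). Oxidative phosphorylation genes such as Sdhd (1.02 ± 0.81) and Cox5a (0.82 ± 0.67) had 0.78 with 26 of 26 higher (adjusted p = 8.14e-06; 0.717 with an estimated correlation). Fatty acid oxidation genes, with Cd36 (1.43 ± 0.61; 211 ± 78.6 against 101 ± 84.5 FPKM), had 0.95 (adjusted p = 0.000272; 0.68 with an estimated correlation), and matrix genes such as Col12a1 (1.70 ± 0.85) and Thbs2 (1.79 ± 0.94) had 0.53 (adjusted p = 0.00156; 0.68 with an estimated correlation).

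Macrophage genes such as Csf1r (0.87 ± 0.40), Adgre1 (0.85 ± 0.42) and Mrc1 (1.52 ± 0.87) had a median of 0.32 with 17 of 18 higher (adjusted p = 0.00399; 0.68 with an estimated correlation). Antigen presentation genes, with H2-K1 (-0.61 ± 0.29) and the immunoproteasome gene Psmb9 (-0.92 ± 0.44), had -0.42 with 16 of 16 lower (adjusted p = 0.00206; 0.68 with an estimated correlation). Oxidative stress genes, with catalase, Cat (1.23 ± 0.68), and the glucose transporter Slc2a1 (-0.86 ± 0.33), had 0.41 (adjusted p = 0.00712; 0.68 with an estimated correlation). The unfolded protein response list, with Chac1 (1.02 ± 0.44) and Asns (1.45 ± 0.94), had 0.12 (adjusted p = 0.0238; 0.68 with an estimated correlation), and erythroid genes, with Pf4 (1.23 ± 0.74), had 0.35 (adjusted p = 0.0358; 0.68 with an estimated correlation). With an estimated correlation 0 of these 11 lists stayed past the threshold, fry called 0, and 0 members passed adjusted over the list alone or over all genes.

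The macrophage difference came from LNA489 13, a library rich in macrophage genes. Without it the macrophage median was -0.21, and the calls of erythroid (0.13), oxidative stress (0.29) and unfolded protein response genes (0.02) ended too, while adipocyte genes had 2.29, fatty acid oxidation 1.62 and muscle 2.54. Without HDL 11 calls ended for antigen presentation (-0.01), matrix (0.18), macrophage (0.14), oxidative stress (0.25), unfolded protein response (0.16) and erythroid genes (0.20), and fatty acid oxidation had 0.63. Without HDL 4 the erythroid call ended (0.03), and adipocyte genes had 2.47, fatty acid oxidation 1.80 and oxidative phosphorylation 1.48. Leaving out LNA489 7 ended the calls of oxidative stress (0.41) and unfolded protein response (0.15), with 0.51 for fatty acid oxidation, 0.44 for oxidative phosphorylation, -0.19 for antigen presentation, 0.55 for macrophage and 0.62 for erythroid genes. Without LNA489 14 muscle genes had 0.76 and macrophage genes 0.52. Without LNA489 19 the erythroid call ended (0.36), with 0.66 for macrophage and 0.28 for unfolded protein response genes. HDL 3 left out gave 0.89 for adipocyte, 0.59 for fatty acid oxidation, 0.43 for oxidative phosphorylation and 0.75 for macrophage genes, and HDL 23 left out gave 0.97 for erythroid genes.

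The reported miR-489-3p targets had a median of -0.10 (adjusted p = 0.985), with Smad3 at -0.28 ± 0.28, Ptpn11 at 0.18 ± 0.27 and Spin1 at -0.10 ± 0.15. Endothelial genes had a median of -0.56 (adjusted p = 0.0802), circadian clock genes 0.20 (0.0832), adhesion and chemokine genes -0.38 (0.182) and interferon response genes -0.17 (0.371), among which the transcription factor Irf1 was -0.74 ± 0.34. Sign differed between the median, the mean and the test for smooth muscle (-0.26, 0.03, up), T and NK cell (-0.02, -0.01, up), neuron and Schwann cell (-0.08, -0.04, up), flow-responsive quiescence (-0.06, -0.09, up), TGF-beta signalling (-0.09, 0.00, up) and miR-92a-3p targets (-0.07, -0.03, up).

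**Figure D4:**
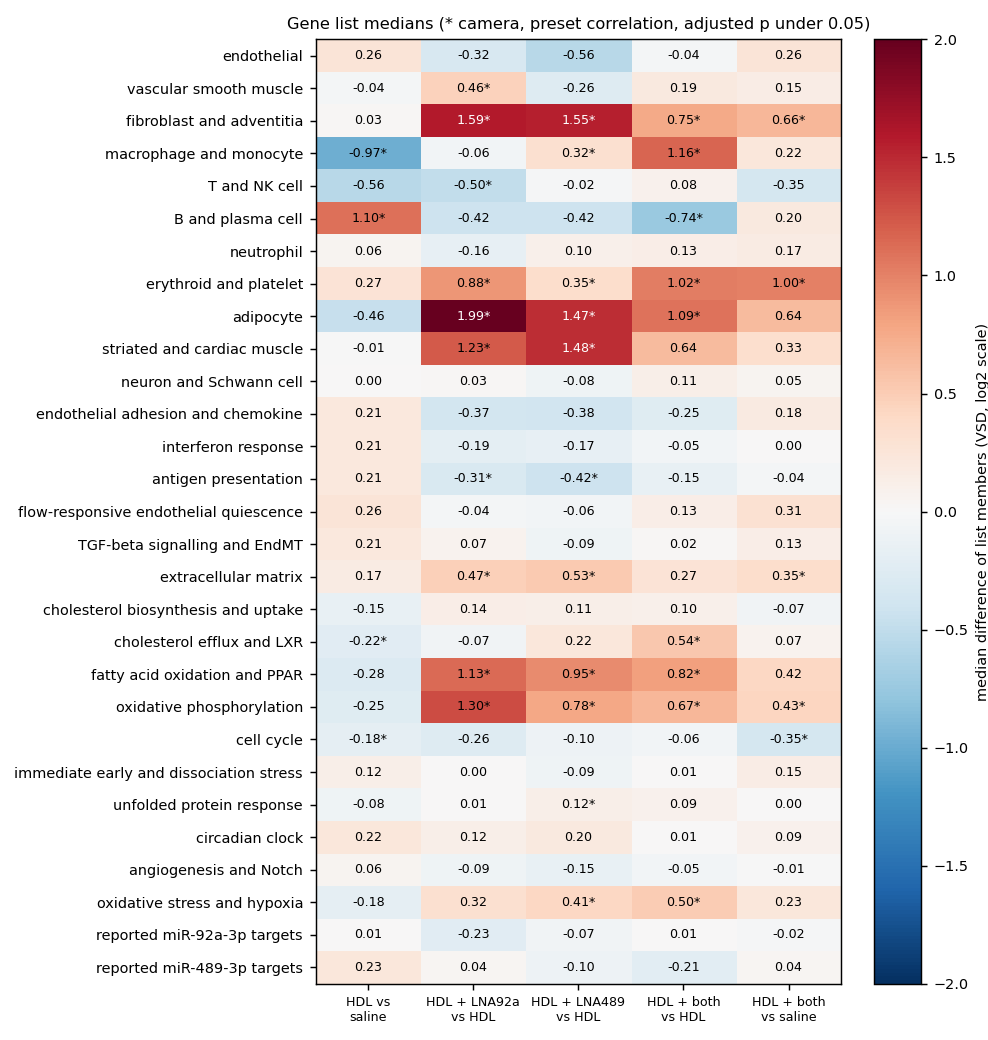
Median log2 difference (variance-stabilized scale) of the members of 29 gene lists in 5 comparisons, where an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Adipocyte medians against HDL were 1.99, 1.47 and 1.09 in LNA92a, LNA489 and the dual group, and 0 lists passed with an estimated correlation.

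The dual group against HDL asks what both inhibitors together add. Epb41l3, a membrane skeleton protein (ENSMUSG00000024044.16, chromosome 17, 69075683 to 69289989), was 22.7 ± 7.13 FPKM in the dual group and 7.64 ± 1.56 in HDL, a log2 difference of 1.41 ± 0.45. The complement genes C1qa (231 ± 98.1 against 112 ± 50.2 FPKM, 0.98 ± 0.40) and C1qc (268 ± 109 against 102 ± 57.0, 1.41 ± 0.53) and the eosinophil-type ribonuclease Ear2 (50.8 ± 16.4 against 14.7 ± 8.75, 1.60 ± 0.52) were higher. Rhebl1 was 0.956 ± 0.209 and 2.63 ± 0.385 FPKM (-0.91 ± 0.23), and the Notch target Hes1 was 2.73 ± 1.24 and 5.18 ± 1.35 (-0.80 ± 0.26).

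Limma called 0 genes, with 416 at unadjusted p under 0.05 (128 higher, 288 lower) and a smallest adjusted p of 0.998. Voom called 0 (558 unadjusted) and arrayWeights 0 (3214 unadjusted), and 316 genes (1.88%) did not overlap against 2.86% by chance. The 416 became 1466 without HDL 4, 801 without dual 21, 243 without dual 10 and 213 without dual 15. With 4 cell type list means as covariates 1 gene passed, the interferon-induced Ifi27l2a, chosen after its values were seen and lower by -1.59 ± 0.22 (adjusted p = 0.0167), against -0.34 (adjusted p = 0.998) without covariates. Other genes with small p were the lysosomal protein Tmem192 (0.76 ± 0.24), biliverdin reductase, Blvra (0.99 ± 0.32), B230118H07Rik (0.78 ± 0.26) and Zfp507 (-0.78 ± 0.21). The pseudogene Gm26925 (-1.40 ± 0.40), the non-coding 2700012I20Rik (-1.16 ± 0.34) and the antisense Gm44623 (-0.92 ± 0.27) are uncertain, and other genes overlap Epb41l3, Ear2, Tmem192, B230118H07Rik, Rhebl1 and Zfp507. Klf2 (-0.25 ± 0.46), Klf4 (0.17 ± 0.54), Itga5 (0.17 ± 0.93), Tgfb2 (0.51 ± 0.40), Mir17hg (-0.47 ± 0.46) and Apoe (0.46 ± 0.51) were not called.

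Macrophage genes were higher in the dual group than in HDL, with a median of 1.16 and 16 of 18 higher (camera adjusted p = 1.05e-08; 0.393 with an estimated correlation), including C1qb (1.38 ± 0.58) and the lysozyme Lyz2 (1.5 ± 0.66; 3580 ± 2080 against 1220 ± 652 FPKM). Cholesterol efflux genes had 0.54 (adjusted p = 0.00052; 0.393 with an estimated correlation), with Pltp (1.16 ± 0.48; 133 ± 45.7 against 62.1 ± 35.7 FPKM), the oxysterol receptor Nr1h3 (0.61 ± 0.33) and Smpdl3a (0.49 ± 0.27). Oxidative stress genes had 0.50 (adjusted p = 0.00118; 0.393 with an estimated correlation), with the peroxidase Gpx1 (0.74 ± 0.33; 435 ± 122 against 248 ± 61.3 FPKM), Srxn1 (0.97 ± 0.51) and Hmox1 (1.28 ± 0.61). Erythroid genes such as Slc4a1 (1.36 ± 0.67) and Alas2 (1.76 ± 0.98) had 1.02 (adjusted p = 0.00374; 0.821 with an estimated correlation). Oxidative phosphorylation, with Cox5a (0.90 ± 0.67) and Cox7a2 (0.87 ± 0.72), had 0.67 with 26 of 26 higher (adjusted p = 2.37e-05; 0.888 with an estimated correlation). Fatty acid oxidation genes, with Cd36 (1.44 ± 0.61) and Fabp5 (1.15 ± 0.79), had 0.82 (adjusted p = 0.000301; 0.888 with an estimated correlation), adipocyte genes, with Lpl (1.29 ± 0.67), 1.09 (adjusted p = 0.000337; 0.888 with an estimated correlation), and fibroblast genes, with Dpt (1.41 ± 1.36), 0.75 (adjusted p = 0.00858; 0.888 with an estimated correlation).

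B and plasma cell genes, with Jchain (-1.66 ± 0.82) and Ms4a1 (-1.02 ± 0.95), had a median of -0.74 with 13 of 14 lower (adjusted p = 0.0102; 0.888 with an estimated correlation). With an estimated correlation 0 of the 9 lists stayed past the threshold, fry called 0, and 0 members passed adjusted over the list alone or over all genes.

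The B cell difference rested on HDL 11. Without it the B cell median was 0.35, and the calls of cholesterol efflux (0.38), oxidative stress (0.32) and fibroblast genes (0.47) ended, with 0.75 for macrophage, 0.70 for adipocyte, 0.51 for erythroid and 0.52 for fatty acid oxidation genes. The macrophage call held on leaving out any of the 8 libraries. Without HDL 4 the erythroid call ended (0.67), and B cell genes had -1.3, adipocyte 2.00, fatty acid oxidation 1.56, fibroblast 1.51 and oxidative phosphorylation 1.38. Without HDL 3 the fibroblast call ended (0.29), and B cell genes had -1.21, adipocyte 0.47, fatty acid oxidation 0.45 and oxidative phosphorylation 0.30. Leaving out dual 8 ended the B cell (-0.48) and fibroblast (0.46) calls, with 0.72 for adipocyte genes, and leaving out dual 15 ended the fibroblast call (0.34), with 0.61, 0.42 and 0.28 for adipocyte, fatty acid oxidation and oxidative phosphorylation genes. Without dual 21 adipocyte genes had 1.91, fatty acid oxidation 1.5, fibroblast 1.52, oxidative phosphorylation 1.32 and erythroid genes 0.60. In place of 9 lists, 14 were called without HDL 23.

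Neither target list was called in the dual group. The miR-92a-3p targets had a median of 0.01 (adjusted p = 0.723), with the deacetylase Sirt1 at -0.44 ± 0.23 and Mtmr4 at -0.45 ± 0.24, and the miR-489-3p targets -0.21 (adjusted p = 0.426), with Spin1 at -0.29 ± 0.15 and Smad3 at -0.39 ± 0.28. Striated muscle genes had 0.64, flow-responsive quiescence 0.13 (0.504) and cholesterol biosynthesis 0.10 (0.281). Sign differed between the median, the mean and the test for endothelial (-0.04, 0.01, up; adjusted p = 0.723), immediate early (0.01, -0.01, down) and angiogenesis and Notch genes (-0.05, -0.02, up; adjusted p = 0.957).

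The dual group against LNA92a and against LNA489 asks what the second inhibitor adds to the first. Against LNA92a, the small nucleolar RNA Snord13 was 1.34 ± 2.67 FPKM and 60.7 ± 47.8 (-2.46 ± 0.56), and without LNA92a 12 it was the 1 gene past the threshold. Gm25911, annotated as a microRNA, was 2120 ± 878 and 5940 ± 2080 FPKM (-1.98 ± 0.38), the 7S RNA gene Rn7s6 -1.18 ± 0.30, and the potassium channel Kcna2 4.54 ± 1.79 and 0.731 ± 0.392 (1.95 ± 0.55). The ribosomal gene Rn18s-rs5 took 16.5% ± 7.16 of reads in LNA92a (6.07% in LNA92a 12) and 5.45% ± 2.76 in the dual group. Whether RNA content plays a part in the small RNAs was not tested. Apoe was higher by 1.08 ± 0.51, and the antisense genes Gm44418 (1.07 ± 0.26) and Gm27003 (1.39 ± 0.36) are uncertain, as is Rn7s6, which another gene overlaps. For this pair limma called 0 genes (415 unadjusted, 244 higher; voom 0 with 311 and arrayWeights 0 with 902), and 480 genes (2.85%) did not overlap, where chance gives 2.86%. The 415 became 273 without dual 21 and 1931 on log2(FPKM + 0.1). Ifi27l2a passed with 4 cell type covariates (adjusted p = 0.0164).

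Against LNA489, the Elongator subunit Elp6 was 1.93 ± 0.791 FPKM in the dual group and 0.552 ± 0.647 (1.3 ± 0.36), the methyltransferase Eef2kmt 8.54 ± 2.33 and 4.11 ± 1.97 (0.90 ± 0.26), and Mir99a 10.2 ± 3.36 where LNA489 is listed at 0. The transporter Slc16a4 was 1.83 ± 0.438 and 3.87 ± 1.79 (-0.91 ± 0.23), the DNA repair gene Nhej1 0.836 ± 0.487 and 3.82 ± 1.34 (-1.21 ± 0.33), and the uncertain Gm45047 -1.15 ± 0.33. In this pair limma called 0 genes (277 unadjusted, 147 higher; voom 0 with 363 and arrayWeights 0 with 758), and 226 (1.34%) did not overlap against 2.86% by chance. The 277 became 906 without LNA489 13. Other genes overlap Eef2kmt (Alg1) and Mir99a (its host Mir99ahg), so both are uncertain.

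LNA489 against LNA92a sets the single inhibitors side by side. The small nucleolar RNA AF357399 was 1.35 ± 1.57 FPKM in LNA489 and 8.45 ± 4.36 in LNA92a (-1.05 ± 0.27), and Rn7s6 was 42.4 ± 22.8 and 72.3 ± 12.6 (-1.17 ± 0.30). Rn18s-rs5 took 7.76% ± 3.66 of reads in LNA489 and 16.5% ± 7.16 in LNA92a, and a part of RNA content in these small RNAs was not tested. Gm44418 (1.25 ± 0.26), Gm43815 (1.03 ± 0.29), Gm27540 (1.08 ± 0.30) and the pseudogene Rps19-ps3 (-0.86 ± 0.23) complete the genes with the smallest p, and all are uncertain, as are AF357399, which lies in Rps16, and Rn7s6. Between the single inhibitors limma called 0 genes (323 unadjusted, 143 higher; voom 0 with 255, arrayWeights 0 with 512 and log2(FPKM + 0.1) 0 with 1044), and 234 (1.39%) did not overlap against 2.86% by chance.

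The dual group against saline sets the whole treatment against none. Ogfod3, a membrane oxygenase, was 8.46 ± 3.13 FPKM in the dual group and 3.04 ± 1.51 in saline (1.04 ± 0.25), and the ATP synthase subunit Atp5g2 9.92 ± 2.41 and 5.11 ± 1.01 (0.71 ± 0.25). Klf2 was higher by 0.86 ± 0.46 and the angiogenic factor Angpt2 lower by -0.99 ± 0.45. The early gene Egr2 was -1.33 ± 0.52 and the zinc finger gene Zfp958 -0.73 ± 0.23. Other genes overlap Ogfod3 (Hexdc) and Atp5g2 (Mir688), which are uncertain, as are the non-coding 2700012I20Rik (-1.17 ± 0.34), Gm27209 (-1.21 ± 0.38) and Gm17300 (0.57 ± 0.21). At adjusted p under 0.05 limma called 0 genes (177 unadjusted, 54 higher; voom 0 with 247 and arrayWeights 0 with 332), and 162 (0.96%) did not overlap against 2.86% by chance. The 177 became 333 without Saline 2, 388 without dual 21 and 100 without dual 15.

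Erythroid and platelet genes were higher in the dual group than in saline, with a median of 1.00 and 11 of 12 higher (camera adjusted p = 5.61e-06; adjusted p = 0.539 with an estimated correlation), led by the band 3 gene Slc4a1 (1.63 ± 0.67), Alas2 (1.75 ± 0.98; 59.9 ± 33.3 against 16.1 ± 10.0 FPKM) and Gp9 (0.69 ± 0.36). Cell cycle genes such as Ccne2 (-0.54 ± 0.33) and Mcm3 (-0.58 ± 0.42) had -0.35 with 30 of 30 lower (adjusted p = 0.00188; 0.913 with an estimated correlation). Matrix genes such as Nid2 (1.01 ± 0.86) had 0.35 with 35 of 38 higher (adjusted p = 0.00402; 0.913 with an estimated correlation), oxidative phosphorylation, with Cox7a2 (0.79 ± 0.72), 0.43 with 26 of 26 higher (adjusted p = 0.00407; 0.913 with an estimated correlation), and fibroblast genes, with Dpt (1.46 ± 1.36), 0.66 (adjusted p = 0.0128; 0.913 with an estimated correlation). Fry called 0 lists, and 0 members passed adjusted over the list alone or over all genes. Sign differed for unfolded protein response (0.00, 0.00, down) and miR-92a-3p targets (-0.02, 0.05, up).

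Saline 9, which had the lowest adipocyte and fibroblast means, and dual 8 decided most of these calls, and 1 list was called without either of them in place of 5. Without Saline 9 the medians were -0.02 for fibroblast, 0.13 for matrix, 0.03 for oxidative phosphorylation and -0.09 for cell cycle genes. Without dual 8 they were 0.39, 0.25, 0.20 and -0.19 in that order, and each of these 4 calls ended in both cases. Without Saline 24 the fibroblast (0.41) and oxidative phosphorylation (0.01) calls ended, as they did without dual 15 (0.32 and 0.07), where matrix genes had 0.23 and cell cycle genes -0.23. There were 10 called lists without Saline 1 (fibroblast 1.06, oxidative phosphorylation 0.87), Saline 2 (1.24, 0.74, cell cycle -0.66) or dual 21 (1.41, 1.03). The erythroid call held on leaving out any of the 8 libraries.

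The non-additive contrast asks whether the dual effect differs from the sum of the single effects. Hrc (-4.00 ± 0.91), Pcp4l1 (-2.63 ± 0.60) and Mlf1 (-3.31 ± 0.85), a gene of heart and other ciliated or contractile cells, were lower than additive, and the arginine methyltransferase Prmt6 was higher (1.63 ± 0.40). The saline libraries, outside this contrast, had 0.112 to 4.09 FPKM of Hrc and 1.27 to 8.29 of Pcp4l1, and the source of these transcripts was not tested. Akirin1-ps (1.53 ± 0.35) and Gm17151 (1.63 ± 0.40) are uncertain, as are Mlf1 and Prmt6, which other genes overlap. Apoe was 1.55 ± 0.73, Tgfb2 -1.18 ± 0.56, Klf2 0.57 ± 0.65, Klf4 -0.30 ± 0.76, Itga5 0.79 ± 1.31 and Mir17hg 0.57 ± 0.66. Limma called 0 genes (530 unadjusted, 263 higher; voom 0 with 531 and arrayWeights 0 with 2205), with a median SE of 0.51. The 530 became 1754 without HDL 4, 1359 without LNA489 13 and 307 without dual 21, and 1300 on log2(FPKM + 0.1). The F-test over the 5 groups called 0 genes (283 unadjusted; voom 0 with 266, arrayWeights 0 with 1718 and log2(FPKM + 0.1) 0 with 552), and 1, Ifi27l2a, with 4 cell type covariates (adjusted p = 0.0431). The 283 became 730 without HDL 4 and 656 without LNA489 13.

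No group of genes with a microRNA site in the 3' UTR was called. Of 12953 genes with a 3' UTR, 972 held the miR-92a-3p site and 1317 the miR-489-3p site. In LNA92a against HDL the miR-92a-3p site genes had a median of -0.065 and the others -0.020, a difference of -0.045 at percentile 29 of 100 control 7-mers, which ran from -0.065 to 0.008. In LNA489 against HDL the miR-489-3p site genes differed from the others by 0.007, at percentile 81 of controls that ran from -0.024 to 0.049. In the dual group the differences were -0.040 (percentile 29) for miR-92a-3p and -0.041 (percentile 33) for miR-489-3p. In HDL against saline, where no inhibitor was given, miR-92a-3p site genes differed by 0.029, at percentile 95 of controls that ran from -0.015 to 0.037, and miR-489-3p site genes by 0.013. With 8-base sites, or the miR-489-3p start moved by 1 base, the differences in these 4 comparisons ran from -0.058 to 0.039. Camera called 0 of 6 tests (smallest adjusted p = 0.762; adjusted p = 0.561 with an estimated correlation).

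The comparisons with HDL share its 4 libraries, which alone makes them resemble each other. Fold changes of LNA92a and LNA489 against HDL had r = 0.77 across genes, which are not independent replicates, where unchanged groups gave a mean of 0.44 (-0.44 to 0.89) and 8 of 100 simulations were as high. Their covariance was 0.185 against 0.093 simulated (10 of 100 as high). With HDL split into separate pairs the mean r was 0.10 (-0.04 to 0.27) and the mean covariance 0.030. LNA92a and the dual group had r = 0.61 (simulated 0.45) and covariance 0.121 (0.101), with split values of -0.08 and -0.034. LNA489 and the dual group had r = 0.67 (0.43) and covariance 0.126 (0.099), with split values of -0.07 and -0.029. Genes at unadjusted p under 0.05 in both, with the same sign, numbered 138, 67 and 92 for the 3 pairs, where simulations gave 121.5, 134.4 and 137.6 and independent lists 11.8, 7.8 and 8.8.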

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

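Among the tests in this part, the weighing of fewer endothelial cells in the dual libraries, the SE between libraries and the correlation within groups as measures of what 2 tests can decide, the fits with cell type covariates and the other tests of Ifi27l2a were chosen only after the results were seen.

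In 270 groups of 4 libraries tested for 1 library far from the other 3, 16 were picked out, where chance picks about 1 in 20 groups, or 13.5. Assigned reads were 17.8 M (mega) in LNA92a 12 and 11.6 to 12.1 M in the other LNA92a libraries. Mitochondrial genes took 21.76% of reads in HDL 4 and 3.23 to 5.95% in the other HDL libraries. LNA489 13 had a fibroblast list mean of 8.98 (others 11.6 to 12.02) and Klf4 at 8.92 (others 10.58 to 10.85). On the same variance-stabilized scale, Saline 24 had Prkar1b at 6.18 (7.02 to 7.18) and Zmym3 at 9.30 (8.69 to 8.79), and Saline 2 had Mir17hg at 5.90 (7.09 to 7.28). LNA92a 5 had Rflnb at 7.88 (8.71 to 8.78) and Gm17151 at 4.66, where the others were at the floor of 4.21. HDL 23 had Zfp770 at 8.22 (7.67 to 7.75). Dual 10 had Pcp4l1 at 7.08 (5.95 to 6.06), and dual 21 had Ankrd1 at 4.21 (6.76 to 7.13), Gm43815 at 4.50 (5.32 to 5.43) and Cep290 at 7.61 (8.06 to 8.14). LNA489 13 had Akirin1-ps at 4.64 with the others at 4.21, and LNA489 7 had Gm26925 at 4.21 (5.43 to 5.6).

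Among genes present in the FPKM table but absent from the variance-stabilized table, Akr1d1, a steroid reductase gene, measured 75 FPKM in dual 10, where the saline libraries had 0 to 60.2, the latter in Saline 2. It is 1 of 1264 such genes with a mean FPKM of at least 0.5, and none of them was tested.

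Oxidative phosphorylation and fat cell genes were higher in both single LNA groups and in the dual group than in HDL with the preset correlation, and with an estimated one 0 of these lists passed (adjusted p = 0.68 to 0.888). These comparisons share the 4 HDL libraries, so they are not separate repeats of 1 result. HDL had the lowest adipocyte mean of the 5 groups, 9.36 ± 1.89 (SD), where saline had 9.81 ± 2.1. With the adipocyte list mean as a covariate, the oxidative phosphorylation median in LNA92a against HDL went from 1.3 to 0.10, but the 2 list means had r = 0.97 within groups, so this test cannot tell perivascular fat carried over in differing amounts from an effect on both gene sets. The 16 adipocyte genes share 0 members with the oxidative phosphorylation list, 11 of the 16 had an FPKM of at least 1 in Saline 9, and within HDL alone the adipocyte mean ran from 7.78 to 12.09. With the share of Rn18s-rs5 reads as a covariate the adipocyte median went from 1.99 to 1.24, and the difference of list means, 1.18 with an SE of 1.4 between libraries, leaves a part played by ribosomal RNA content open. An effect of the inhibitors on fat or mitochondrial genes stays open and untested.

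The macrophage list was lower in HDL than in saline and than in the dual group with the preset correlation, but not past the threshold with an estimated one (adjusted p = 0.499 and 0.393). Without HDL 11, the library rich in B cell transcripts, the median of the dual group against HDL went from 1.16 to 0.75, above the 0.58 set as the bound for this explanation, and the preset call held without any 1 of the 8 libraries. The difference of list means without HDL 11, 0.74 with an SE of 0.41 between libraries, reaches below that bound, so the part of HDL 11 stays open. Fewer endothelial cells in the dual libraries would lower the endothelial list, whose mean was 10.34 ± 0.96 (SD) in the dual group and 10.33 ± 1.82 in HDL, and would raise other cell types together, but the B cell median was -0.74 and turned to 0.35 without HDL 11, and the endothelial median ran from -0.73 to 0.57 on leaving out 1 library, so this stays open. An effect of treatment on macrophages in the vessel wall stays open and untested.

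Ifi27l2a, an interferon-induced gene chosen after its values were seen, was lower in the dual group than in HDL by -1.59 (adjusted p = 0.0167) with 4 cell type lists as covariates and by -0.34 (adjusted p = 0.998) without them. With the slopes taken from the other 12 libraries the difference was -1.74, and the lowest HDL value (10.54) lay above the highest dual value (9.30). The gap thus did not need slopes fitted to these 8 libraries. The gene was picked for its gap in the same 8 libraries, though, so their separation is no support of its own. Leaving out 1 of the 8 libraries gave a difference nearest to 0 of -1.52, so no single library carried its size. The adjusted p ran from 0.0382 without dual 10, the 1 fit of 8 past the threshold, to 0.119, so the call was lost in the other fits. Of 35 splits of the 8 libraries, 2 called at least 1 gene in this fit (1 in the real split and at most 1 in the others), so chance cannot be excluded. An effect of the 2 inhibitors on this gene stays open and untested.

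Chance could not be excluded for any count of genes or lists when the libraries were split in other ways. For genes at unadjusted p under 0.05, the real split or a larger result came up in 34 of 35 splits for HDL against saline (281 genes; highest other 4484), 16 for LNA92a against HDL (595; 4447), 23 for LNA489 against HDL (638; 5394) and 21 for the dual group against HDL (416; 5085). The counts were 10 of 35 for the dual group against LNA92a (415; 1933), 27 against LNA489 (277; 2154) and 33 against saline (177; 3397), 34 for LNA489 against LNA92a (323; 1673), 45 of 100 for the non-additive contrast (530; 4303) and 88 of 100 for any difference among the groups (283; 4613). For called lists they were 35 of 35 for HDL against saline (4 lists; highest other 19), 28 for LNA92a (10; 16), 22 for LNA489 (11; 18) and 31 for the dual group (9; 15) against HDL, and 32 for the dual group against saline (5; 15). Other splits called up to 932, 399, 1933 and 1510 genes at adjusted p under 0.05 in HDL against saline and in LNA92a, LNA489 and the dual group against HDL, where limma called 0 in the real split, and any gene at all in 3, 2, 1 and 1 of the 35 splits. In the splits of the other 4 pairs limma called 0. The few splits with genes past the threshold were all of pairs with HDL, which share its 4 libraries. What sets these splits apart was not tested.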

How the results depend on the processing

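Voom, the 4 cell type covariates, leaving aside 3 libraries and the fit on libraries with an endothelial mean above their adipocyte mean were chosen after the data were seen. Of 231 alternative fits, 227 called 0 genes and 4 called 1. With 4 cell type covariates 1 gene was called, Ifi27l2a, in the dual group against HDL, in the dual group against LNA92a and among the 5 groups. Leaving out 1 library gave 0 to 1 genes for the dual group against LNA92a (Snord13, without LNA92a 12) and 0 elsewhere. Unadjusted counts in limma were 177 to 638 per pair of groups, and voom and arrayWeights called 0. These counts moved several-fold with single libraries and scales: against HDL they were 2860 (LNA92a), 2297 (LNA489) and 1466 (dual) without HDL 4, and LNA489 had 1317 without LNA489 13. On log2(FPKM + 0.1) LNA92a against HDL had 2201, and with the smooth muscle covariate 264. With 4 covariates HDL against saline had 812, the dual group against saline 613 and LNA489 against LNA92a 911. On libraries whose endothelial mean exceeded their adipocyte mean, LNA92a against HDL had 1714 and HDL against saline 427, with 0 called. That rule kept HDL 11 (endothelial mean 9.23) and left out dual 10 (10.69), so it is not a cut on endothelial content alone. Of 14486 values, under alternatives, of the genes that the fixed rule names, 14127 kept their direction and side of the threshold, 358 changed sign with neither value past it, 1 passed it (Snord13) and 0 reversed past it. Ifi27l2a, named outside that rule, is not in this tally. Of the list medians, 1249 were the same, 254 moved, 157 were stronger, 151 weaker and 54 reversed. The seed-site tests called 0 throughout.

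Camera with an estimated correlation called 0 lists in the 5 comparisons, with a median estimated correlation of 0.28 between list members where the preset is 0.01, and fry called 0 in each. Log2(FPKM + 0.1) gave 7 lists in HDL against saline, where 4 were called. With 4 covariates there were 9 lists in HDL against saline, 3 in LNA92a against HDL and 8 in the dual group against saline, and with 3 libraries left aside 8 and 9 in HDL and the dual group against saline. The 4 covariates are themselves means of tested lists (endothelial, adipocyte, macrophage and B cell). That fit removes the mean group difference of those lists by construction, so it does not test them. Leaving out 1 library gave 3 to 14 lists in HDL against saline, 7 to 13, 9 to 16 and 7 to 14 in LNA92a, LNA489 and the dual group against HDL, and 1 to 10 in the dual group against saline.

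Medians counted as reversed changed sign with a call in at least 1 of the 2 fits, and other sign changes, with no call in either, are among the 254 that moved. The cause was not tested. The fibroblast and oxidative phosphorylation means each had r = 0.97 with the adipocyte mean, 1 of the 4 covariates. The cholesterol efflux mean had r = 0.92 with the macrophage mean, another of them. Sign changes of those lists with 4 covariates therefore cannot be told from removal of that shared variation. Under log2(FPKM + 0.1), oxidative stress in LNA92a against HDL was -0.09. With 4 covariates, HDL against saline had cholesterol efflux at 0.03 and oxidative phosphorylation at 0.22. LNA92a against HDL had fibroblast -0.13, T and NK cell 0.24, matrix -0.08, fatty acid oxidation -0.10 and cell cycle 0.25. LNA489 against HDL had T and NK cell 0.57, flow-responsive quiescence 0.22, fatty acid oxidation -0.07, oxidative phosphorylation -0.21 and cell cycle 0.24. The dual group against HDL had fibroblast -0.18, TGF-beta -0.24, matrix -0.38, oxidative phosphorylation -0.06, cell cycle 0.29, immediate early -0.20 and oxidative stress 0.00. With HDL 11, Saline 2 and dual 10 left aside, HDL against saline had B cell -0.13 and cholesterol efflux 0.01. LNA92a against HDL had T and NK cell 0.04, B cell 0.63, antigen presentation 0.07 and matrix -0.05, LNA489 had T and NK cell 0.51, B cell 0.75 and cell cycle 0.33, and the dual group had B cell 0.36, TGF-beta -0.29, matrix -0.12, cell cycle 0.25 and immediate early -0.17. On leaving out 1 library, lowest to highest, medians that reversed in this sense were -0.89 to 0.65 for fibroblast and -0.68 to 0.16 for cell cycle in HDL against saline, and -0.02 to 1.41 for fibroblast in the dual group against saline. They were -1.24 to 0.04 for T and NK cell, -0.98 to 0.63 for B cell, -0.57 to 0.07 for antigen presentation and -0.05 to 0.66 for matrix in LNA92a against HDL. LNA489 against HDL had -0.64 to 0.51 for T and NK cell, -0.94 to 0.75 for B cell, -0.51 to 0.33 for cell cycle and -0.21 to 0.75 for macrophage. The dual group against HDL had -0.73 to 0.57 for endothelial, -1.3 to 0.35 for B cell, -0.24 to 0.22 for TGF-beta, -0.15 to 0.59 for matrix and -0.39 to 0.36 for cell cycle.

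Count models (DESeq2, edgeR) were not run, since the deposited values are not counts. The fit on libraries with an endothelial mean above their adipocyte mean was made for 2 comparisons, with 1 library left in LNA489 and in the dual group. At 11.6 to 21.4 M (mega) assigned reads per library, Calcr had at most 5 reads and could not be compared.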

Other observations

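The adrenal, pancreatic and lesion markers of this part were chosen only after the libraries had been seen, so their values describe single libraries and were not tested between groups.

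A few libraries held transcripts of organs that lie beside the aorta. Cyp11b1, the last enzyme of glucocorticoid synthesis, measured 376 FPKM in Saline 2 and 275 in dual 10, with a median of 0.0445 over the 20 libraries, and the steroid dehydrogenase Hsd3b1 measured 685 in Saline 2. Summed over 7 adrenal cortex genes, Saline 2 had 2160 FPKM and dual 10 had 1720, and the next library, LNA489 14, had 24.4. Nr5a1, the transcription factor of steroid-making cells, measured 15.4 FPKM in Saline 2 and 10.1 in dual 10, and Akr1cl 33.9 and 22.4. Chga, a gene of adrenal medulla granules, measured 81.8 FPKM in Saline 2 and 6.69 in HDL 23, and Th, which makes the catecholamine precursor, 11.5 in Saline 2 and 1.57 in LNA489 19. Pancreatic enzyme genes, summed over 7, had 672 FPKM in Saline 2, 467 in LNA489 13 and 167 in LNA489 14 against a median of 2.75, among them the elastase Cela2a (47.2 in Saline 2, 30.6 in LNA489 13) and the lipase cofactor Clps (49.6 and 36.2).

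Genes of foam cells in lesions varied too. Summed over 8 such genes, LNA489 13 had 6620 FPKM, Saline 9 had 5080 and dual 10 had 2720, against a median of 859 and 32.1 in LNA92a 5. Mesothelial genes, summed over 5, reached 643 FPKM in LNA489 14, 283 in dual 15 and 267 in HDL 4, against a median of 132. The immunoglobulin gene Ighv1-72 measured 125 FPKM in HDL 11 and 4.3 in LNA489 14, and Igkv3-5 measured 106 in HDL 11 and 19.2 in dual 15.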
